A study of Mus musculus with 12 samples.

How the data were processed

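Total RNA from side population cells of mouse extraocular muscle (EOM, 6 preparations) and tibialis anterior muscle (TA, 6 preparations) was amplified in 2 rounds, labelled with biotin and hybridized to Affymetrix whole-genome mouse arrays, 1 array per preparation, per the labels' protocols. The submitters' processing notes name MAS5, which summarizes the probes of each probe set into 1 signal. The deposited values are signal intensities on a linear scale: in each of the 12 columns the mean, trimmed by 2% at each end, was 150, so that every array had been scaled as a whole to that value by the authors. Because the scaling sets all arrays to 1 mean, an array with little labelled target has its background raised with its signal. Present and absent calls are not in the table, and scan dates and the sex and age of the mice are not in the labels used here. Groups and replicate numbers (0, 1, 2, 3, 5 and 6 in each group) come from the sample titles, and the labels state that the preparations were isolated independently. No 2 columns held identical values, and 0 columns were left unused.

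The table held 45101 probe sets, of which 64 were controls. Genes were named through the platform annotation: 34958 probe sets had 1 gene symbol, 932 several and 9160 none, and those with several or none were tested but not named. Symbols were compared through their gene identifiers with current names (assembly GRCm38.p6, used for names only); 0 changed and 204 were kept without a match, giving 18194 named genes. No genome coordinates are given, since the array's build was not given in the sources used here.

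Signals were transformed as log2(signal + 16), with no further scaling, as the arrays shared a trimmed mean. Fold changes are on this scale and understate the change of genes with low signal. Controls were removed, and the 40% of probe sets with the lowest mean over the 12 arrays were not tested, leaving 27022 probe sets. EOM and TA were compared with limma 3.58.1 in R 4.3.3 (linear model per probe set, empirical Bayes moderation with an intensity trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values of genes and lists come from limma; fold changes are EOM minus TA with the moderated standard error. A gene was represented by its probe set with the highest mean over the 12 arrays, giving 13067 genes; among 5675 genes with several tested probe sets, 0 had calls in both directions. In 4 named genes (Hoxa9, Jag1, Mcm3 and Tpm2) the estimates of different probe sets differed in sign. Of 57 named genes with several tested probe sets, some had another probe set that changed far less than the one used. Examples are Cav2 (-0.81), Lyz1 (-0.04), Pdgfb (-0.21), Flt4 (-0.50) and Tbx3 (-0.40). In others the further probe sets changed alike or more.

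Before the data were examined, 34 gene lists (pathways, patterning genes and cell type markers, 881 entries, of which 56 had no named probe set) were fixed, with the test design and most alternatives. Lists were tested with camera (preset correlation between genes of 0.01, two-sided, Benjamini-Hochberg over the 34 lists), with camera using an estimated correlation, and with fry. Camera compares a list with the other genes, while fry tests it against no change, so their p-values answer different questions. Counts of members are given after adjustment over all tested probe sets and, where stated, adjusted over the list alone. Of the 16 lists past the threshold with camera, 3 stayed past it with the estimated correlation: endothelial, pericyte and smooth muscle, and Notch. The estimated correlation was -0.0362 for the side population list and -0.0118 for Notch, under the preset 0.01, yet their p-values rose. The loss of lists with this setting therefore cannot be credited to correlation between genes alone. Genes named in the text followed a rule fixed at the same time: the 12 largest increases and 12 largest decreases among genes past the threshold without overlap between the groups, up to 4 members past the threshold from each list with the largest change, and 20 genes of interest whatever their result. Of these 20, 6 could not be tested: Pax7, Myf5 and Tbx4 fell under the level filter, and the others were not analysed here.

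The similarity of the arrays was tested by exact permutation over all 462 splits into 6 and 6, and array measures (median signal, hybridization controls, 3' to 5' ratios) over all 924 assignments. Alternatives changed 1 choice at a time: the added constant (1 or 64), quantile normalization, median centring, no filter or a filter on 60%, no intensity trend, array weights, the replicate number as a fixed or random block, the 3' to 5' ratio as a covariate, the mean of a gene's probe sets, and each array or each replicate number left out. Leaving out the 3 arrays with a median signal above 50 was added after seeing the data. The fit was tested on simulated data for EOM against TA with the spread of the real probe sets and arrays (27022 probe sets, 100 changed 2-fold and 100 changed 4-fold). It called 9% of the 2-fold and 63% of the 4-fold changes, all in the right direction, with 1 unchanged probe set called. The simulated share of changed probe sets was smaller than the 8.23% called in the data, so these percentages may be too low. The simulated noise was independent between probe sets, so the 1 false call does not cover deviations that an array's probe sets share. Among 34 simulated lists of 20 independent probe sets, camera with the preset correlation called the 1 shifted list and also 1 unchanged list. Arrays carry no read depth; their number limits the precision. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.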

Results

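Gene expression was measured in side population cells from 2 mouse muscle sources, the extraocular muscles that move the eye (EOM) and the tibialis anterior of the hind limb (TA). Side population cells are the small fraction of a dissociated tissue that pumps out the dye Hoechst, a property shared with stem and progenitor cells of several tissues. Per the labels, 6 separately isolated preparations of each source were hybridized, 1 preparation per array, so that 12 arrays in 2 groups of 6 were compared. The comparison asks how the side population of extraocular muscle differs from that of a limb muscle. Extraocular muscles arise in the head rather than from the somites, and they are spared in several muscular dystrophies. No count or depth stands behind an array signal, and the precision of every value below is set by the 6 arrays per group.

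Most arrays were alike in overall signal, and 3 stood apart. The median signal was between 31.2 and 43.4 on 9 arrays, and it was 87.2 on EOM 1, 69.6 on TA 3 and 63.2 on TA 5. The hybridization controls, bacterial transcripts added to every sample in a fixed amount, had a mean signal of 8530 on EOM 1, 6225 on TA 3 and 3883 on TA 5, against at most 2346 on the other arrays. The ratio of 3' to 5' beta-actin signal, a measure of how far the amplified RNA was shortened, was 30.7 ± 36.7 in EOM and 62.8 ± 61.9 in TA (SD, n = 6, exact permutation test on the log2 scale, two-sided, p = 0.398). For Gapdh the ratio was 14.8 ± 6.67 in EOM and 18.1 ± 9.60 in TA (SD, n = 6, exact permutation p = 0.675). Median signal (exact permutation p = 0.693, n = 6 per group) and hybridization control signal (exact permutation p = 0.643, n = 6 per group) did not pass either. The Benjamini-Hochberg adjusted value was 0.693 for all 4 array measures.

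The arrays separated by muscle. The mean Pearson correlation of log2 signal across probe sets was 0.842 between EOM arrays, 0.856 between TA arrays and 0.796 between arrays of different groups. The within-group mean exceeded the between-group mean by 0.0535, a difference that few of all possible splits of the 12 arrays into 6 and 6 reached (exact permutation test, one-sided, p = 0.00649). The first principal component held 37.4% of the variance and set EOM 1, TA 3 and TA 5 apart from the other arrays. The second held 23.7% and had all 6 EOM arrays on one side and all 6 TA arrays on the other. EOM 1 correlated with the other EOM arrays at a mean of 0.632, and its nearest array was TA 3 at 0.689.

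**Figure D1:**
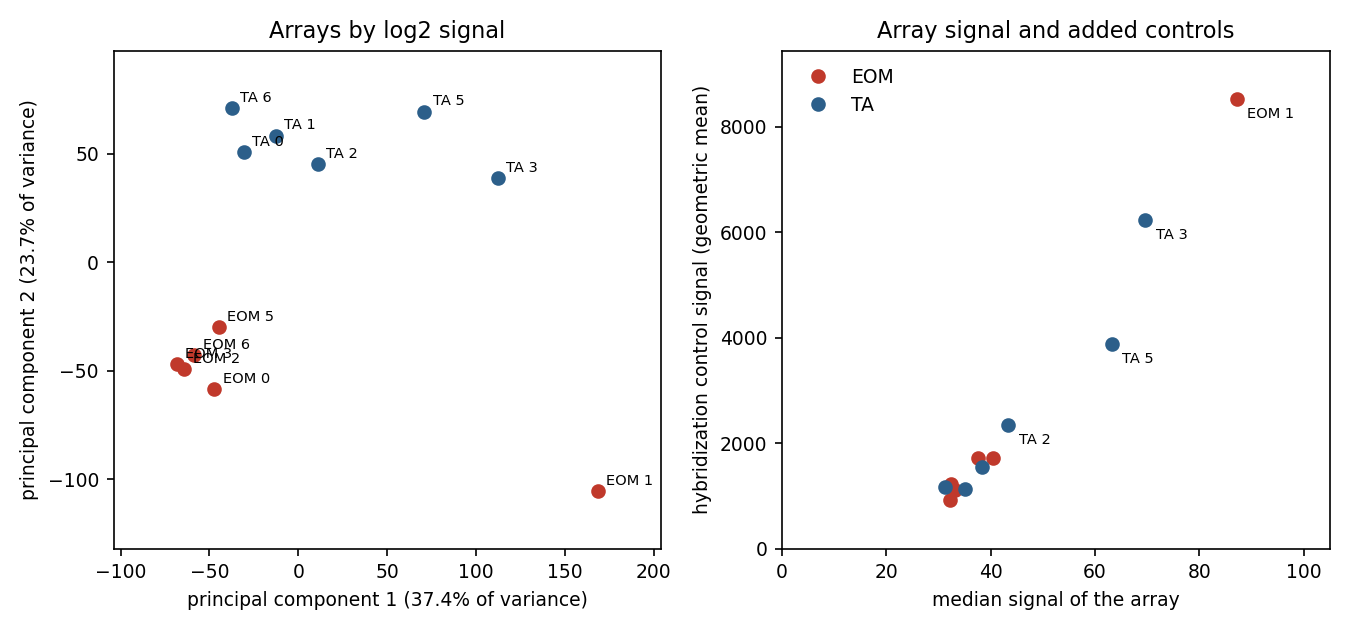
Left, the 12 arrays on the first and second principal components of the log2 signal (arbitrary units, with the percent of variance on each axis); right, the median signal of each array against the geometric mean signal of its hybridization controls (both linear signal). EOM arrays are red and TA arrays blue; the second component separates the muscles, and EOM 1, TA 3 and TA 5 have median signals of 87.2, 69.6 and 63.2 against at most 43.4 elsewhere.

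EOM and TA side population cells differed in many genes. Of 13067 genes tested, 1419 passed the threshold (limma, adjusted p under 0.05), 529 of them higher and 890 lower in EOM, and 1280 of the 1419 differed at least 2-fold. The 12 genes that rose most in EOM with no overlap between the groups were led by Epyc, a cartilage-type proteoglycan, Phex, an endopeptidase known from phosphate handling in bone, and Pi16, a peptidase inhibitor of fibroblasts. Epyc had a signal of 3465 ± 1564 in EOM and 22.3 ± 13.7 in TA (SD, n = 6), a log2 fold change of 6.28 ± 0.48 (SE, and adjusted p = 3.24e-07). For Phex the log2 fold change was 5.79 ± 0.60 (adjusted p = 5.73e-06), and for Pi16, at 19584 ± 8523 against 466 ± 354 (SD, n = 6), it was 5.55 ± 0.39 (adjusted p = 1.88e-07). The rest of this group were the receptor Dner (4.32), the secreted neuronal protein Lgi1 (3.97), the aldehyde oxidase Aox3 (3.75), the elastic fibre protein Mfap4 (3.65), the glutathione transferase Gsta4 (3.54), and the neurofilament subunit Nefm (3.50), as log2 fold changes. The Iroquois transcription factors Irx3 (3.80), Irx2 (3.62) and Irx5 (3.41) completed the group.

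The 12 genes that fell most in EOM with no overlap between the groups were led by Timp4, an inhibitor of matrix metalloproteinases, at 79.8 ± 72.5 in EOM and 5600 ± 2161 in TA (SD, n = 6, log2 fold change -6.10 ± 0.41, SE, and adjusted p = 1.27e-07). Next came Aplnr, the apelin receptor of vascular cells, at -5.33 ± 0.43 (adjusted p = 4.48e-07). The water channel Aqp1 was at 292 ± 156 against 10074 ± 4542 (SD, n = 6, -5.07 ± 0.40, adjusted p = 3.43e-07). The others were the secreted vascular factor Egfl7 (-4.75), the matrix protein Chad (-4.50), the caveolar protein Cav2 (-4.45, with its other tested probe set at -0.81) and the lipoprotein lipase anchor Gpihbp1 (-4.44). Also in this group were the adhesion receptors Adgrl4 (-4.31) and Adgrf5 (-4.17), the fatty acid carrier Fabp5 (-4.11), Depp1 (-4.11) and the lipoprotein receptor Scarb1 (-4.10). At the level of probe sets, 2225 of 27022 passed, 866 higher and 1359 lower in EOM. In 5.43% of all tested probe sets the 6 EOM arrays did not overlap the 6 TA arrays, where chance gives 0.216%. EOM 1 held these counts down: without it 4361 probe sets passed, 2128 higher and 2233 lower, a share of 48.8% higher against 38.9% with all arrays. Without EOM 1, TA 3 and TA 5, a setting chosen after the data were seen, 4675 passed, 2256 higher and 2419 lower. All 1419 genes called with 12 arrays were also called in the same direction without EOM 1, where 2675 genes passed.

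**Figure D2:**
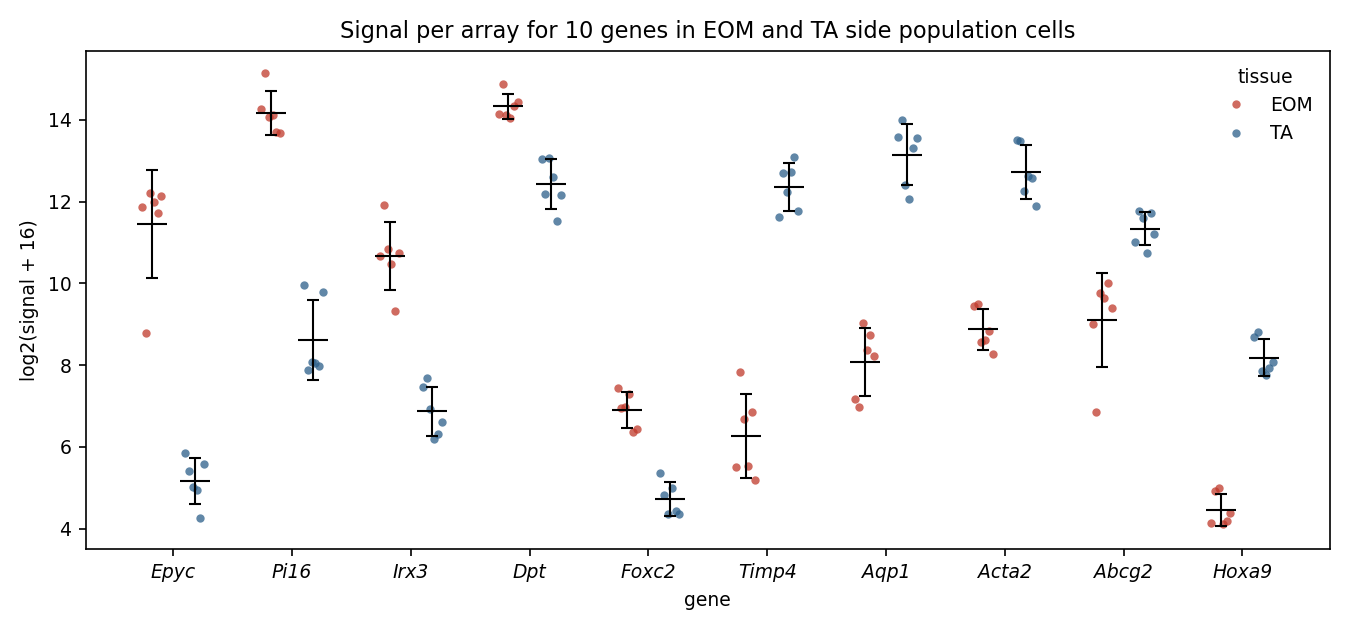
The log2 signal (after adding 16) of 10 genes in each of the 6 EOM arrays (red) and 6 TA arrays (blue); each point is an array, and the black lines give the mean and SD of the group. Epyc, Pi16, Irx3, Dpt and Foxc2 were higher in EOM and Timp4, Aqp1, Acta2, Abcg2 and Hoxa9 lower, with no overlap between the groups.

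Endothelial markers and those of pericytes and smooth muscle had the lowest medians of the 34 lists in EOM. Of 31 endothelial markers tested, 28 fell and 0 rose (29 fell when adjusted over the list alone). Their median log2 fold change was -3.08 (camera adjusted p = 1.21e-38, and adjusted p = 0.0201 with an estimated correlation). Besides Aqp1, Egfl7 and Gpihbp1, the complement receptor-like protein Cd93 fell to 114 ± 39.5 from 2411 ± 1250 in TA (SD, n = 6, -4.10 ± 0.37, adjusted p = 1.24e-06). Pecam1, the platelet-endothelial adhesion molecule, was at -1.84 ± 0.60 and did not pass (adjusted p = 0.0702); leaving out EOM 5, TA 2 or TA 3 brought it past, to 0.0187 at the lowest of these fits. So did the 3' to 5' ratio as a covariate (-2.29, adjusted p = 0.00211), array weights (-2.10, adjusted p = 0.00230) and leaving out EOM 1, TA 3 and TA 5 (-2.23, adjusted p = 0.0119). Among 19 pericyte and smooth muscle markers 15 fell and 0 rose (17 fell when adjusted over the list alone). Their median was -2.09 (camera adjusted p = 9.92e-15, and adjusted p = 0.0201 with an estimated correlation). They included smooth muscle myosin Myh11 (-4.03 ± 0.52, adjusted p = 5.08e-05) and the chloride channel Ano1 (-3.97 ± 0.33, adjusted p = 6.07e-07). Falling too were the pericyte regulator of G-protein signalling Rgs5 (-3.96 ± 0.31, adjusted p = 4.32e-07) and smooth muscle actin Acta2 (-3.85 ± 0.32, adjusted p = 5.41e-07). Pdgfrb, a receptor of pericytes and fibroblasts, was at -0.51 ± 0.36 (adjusted p = 0.506), and at -0.78 (adjusted p = 0.0773) without EOM 1. It passed only without EOM 1 and TA 1 together. The 8 lymphatic endothelial markers tested gave 2 that fell, Stab1 (-2.64) and Flt4 (-2.30), and the list did not pass (camera adjusted p = 0.174); without EOM 1 it did, at 0.0467.

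With all 12 arrays, the markers by which side population and stem cells are known were lower or unresolved in EOM. Abcg2, the transporter that exports the Hoechst dye, was at 650 ± 322 in EOM and 2668 ± 728 in TA (SD, n = 6, -2.23 ± 0.42, adjusted p = 0.00206). Of 19 genes on the side population and stem cell list 6 fell and 0 rose (8 fell when adjusted over the list alone, and 9 fell and 2 rose without EOM 1). Among them were the laminin receptor subunit Itga6 (-3.81 ± 0.28, adjusted p = 2.24e-07), the membrane protein Prom1 (-2.49 ± 0.35, adjusted p = 0.000117) and the haematopoietic and endothelial transcription factor Tal1 (-1.77 ± 0.38, adjusted p = 0.00542). Itga6 and Abcg2 are also known from endothelial cells, whose markers fell with a median of -3.08. The list passed (median -0.57, camera adjusted p = 0.0216, and adjusted p = 0.0912 with an estimated correlation), and it no longer did without EOM 1, at 0.0571. Abcb1a, a multidrug transporter, was at -0.57 ± 0.40 (adjusted p = 0.489), and at -0.91 (adjusted p = 0.0272) with the 3' to 5' ratio as a covariate and -0.36 (adjusted p = 0.551) without EOM 1. The receptor Kit was at -0.29 ± 0.37 (adjusted p = 0.765), and at 0.417 to 1.54 times that value with 1 array left out. Its mean signals were low, at 29.0 in EOM and 40.1 in TA. Cd34, a sialomucin of progenitor and endothelial cells, was at 1.04 ± 0.53 and did not pass with all arrays (adjusted p = 0.300). EOM 1 alone was low for it, and without that array the log2 fold change was 1.65 ± 0.25 (adjusted p = 0.000112). Ly6a was not analysed here.

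Several leukocyte and macrophage markers were also lower in EOM. Among 15 pan-leukocyte and lymphocyte markers 7 fell and 0 rose (12 fell when adjusted over the list alone), with a median of -1.11 (camera adjusted p = 9.38e-07, and adjusted p = 0.0912 with an estimated correlation). Ptprc, the pan-leukocyte phosphatase CD45, was at 172 ± 176 in EOM and 940 ± 414 in TA (SD, n = 6, -2.63 ± 0.46, adjusted p = 0.000945). The tetraspanin Cd53 was at -2.42, the actin-binding Coro1a at -2.23 and the interleukin receptor Il7r at -2.07. Of 20 macrophage and monocyte markers 7 fell and 0 rose (11 fell when adjusted over the list alone, median -1.24, camera adjusted p = 9.68e-06, and adjusted p = 0.147 with an estimated correlation). Among those that fell were lysozyme Lyz1 (-4.27 ± 0.92, adjusted p = 0.00568), the protease Ctss (-3.47 ± 0.50, adjusted p = 0.000155) and the signalling adaptor Tyrobp (-2.90 ± 0.58, adjusted p = 0.00336). Antigen presentation genes gave 6 lower and 1 higher of 17 (the same numbers when adjusted over the list alone, median -0.59, camera adjusted p = 0.00542, and adjusted p = 0.219 with an estimated correlation). Without EOM 1, TA 3 and TA 5 the list was at 0.0619. The class II genes H2-Aa (-3.52 ± 0.33, adjusted p = 1.99e-06) and H2-Ab1 (-2.70 ± 0.46, adjusted p = 0.000787) and the class II chaperone Cd74 (-1.82 ± 0.38, adjusted p = 0.00426) fell. Neutrophil and mast cell markers did not pass as a list (11 tested, 1 higher and 2 lower, camera adjusted p = 0.757); histidine decarboxylase, Hdc, fell (-3.17 ± 0.54, adjusted p = 0.000768). The 3 erythroid markers tested did not pass, alone or as a list (camera adjusted p = 0.757; 1 lower when adjusted over the list alone).

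Several fibroblast markers moved the other way. Of 27 fibroblast and fibro-adipogenic progenitor markers 8 rose and 1 fell in EOM (10 and 2 when adjusted over the list alone, 14 and 1 without EOM 1). Their median was 0.62 (camera adjusted p = 0.000117, and adjusted p = 0.0912 with an estimated correlation). Besides Pi16, the matrix protein Dpt rose to 21020 ± 4933 from 5908 ± 2301 in TA (SD, n = 6, 1.90 ± 0.30, adjusted p = 0.000327). So did the dipeptidase Dpep1 (2.07 ± 0.40, adjusted p = 0.00254) and the stromal sialomucin Cd248 (2.02 ± 0.37, adjusted p = 0.00135). Pdgfra, the receptor that marks fibro-adipogenic progenitors, was at 1.18 ± 0.32 (adjusted p = 0.0282). Of the 12 fits with 1 array left out, 8 ended that call, with an adjusted p of 0.0776 at the highest. Without EOM 1 Pdgfra was at 1.45 (adjusted p = 0.000211). All 3 of its tested probe sets passed with all arrays, at 1.18 to 2.01, the one used here being the lowest. Extracellular matrix and remodelling genes went both ways, 10 higher and 6 lower of 43 (15 and 8 when adjusted over the list alone, 17 and 6 without EOM 1). The list did not pass (median 0.18, camera adjusted p = 0.142), except without EOM 1 or TA 0, where the lowest adjusted p was 0.0204. Its largest changes were the collagen-binding proteoglycan Fmod (-3.41 ± 0.55, adjusted p = 0.000429) and the basement membrane chain Col4a2 (-3.29 ± 0.24, adjusted p = 2.24e-07). They were followed by tenascin C, Tnc (-2.36 ± 0.40, adjusted p = 0.000784), and fibulin 1, Fbln1 (2.26 ± 0.46, adjusted p = 0.00398).

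Several genes of detoxification and antioxidant defence were higher in EOM. Of 26 tested 6 rose and 1 fell (10 and 2 when adjusted over the list alone, 12 and 1 without EOM 1), with a median of 0.54 (camera adjusted p = 7.55e-05, and adjusted p = 0.0912 with an estimated correlation). Gsta4, which conjugates products of lipid peroxidation, was at 638 ± 247 in EOM and 45.7 ± 34.6 in TA (SD, n = 6, 3.54 ± 0.45, adjusted p = 4.31e-05). The cytochrome Cyp1b1 (3.12 ± 0.42, adjusted p = 8.66e-05), the extracellular superoxide dismutase Sod3 (2.86 ± 0.36, adjusted p = 4.41e-05) and haem oxygenase, Hmox1 (2.56 ± 0.49, adjusted p = 0.00211), rose too. Oxidative phosphorylation genes had a small shift down (36 tested, 3 lower and 0 higher, 5 lower when adjusted over the list alone and 9 lower without EOM 1, median -0.36, camera adjusted p = 0.00289, and adjusted p = 0.0912 with an estimated correlation). The largest changes were in Uqcrc2 of complex III (-1.20 ± 0.21, adjusted p = 0.000884) and the cytochrome oxidase subunit Cox5a (-1.17 ± 0.24, adjusted p = 0.00473). Glycolysis genes did not pass as a list (15 tested, camera adjusted p = 0.673); hexokinase 2, Hk2, was the only member called (1.52 ± 0.37, adjusted p = 0.0138). Without EOM 1 the list had 1 higher and 4 lower.

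Several Hox genes were lower and several genes of head patterning higher in EOM. Of 14 Hox genes tested, the transcription factors of trunk and limb position, 6 fell in EOM and 0 rose (12 fell when adjusted over the list alone and 11 without EOM 1). Their median was -1.20 (camera adjusted p = 5.00e-07, and adjusted p = 0.0965 with an estimated correlation). Hoxa9 was at 6.67 ± 6.58 in EOM and 288 ± 101 in TA (SD, n = 6, -3.73 ± 0.30, adjusted p = 4.48e-07), while its other tested probe set was at 0.08. Hoxb4 was at -2.52 ± 0.36 (adjusted p = 0.000139) and Hoxd8 at -1.76 ± 0.27 (adjusted p = 0.000318). Hoxa10 (-1.27 ± 0.45, adjusted p = 0.102) and Hoxc10 (-1.24 ± 0.49, adjusted p = 0.144) did not pass with all arrays. Without EOM 1 both did, at 0.00619 and 0.00415. Their mean signals were low, for Hoxa10 22.6 in EOM and 70.6 in TA, and for Hoxc10 29.15 and 67.9. Genes of the head mesoderm, neural crest and the region around the eye gave 5 higher and 0 lower of 19 (10 higher and 1 lower both when adjusted over the list alone and without EOM 1). Their median was 0.93 (camera adjusted p = 9.37e-05, and adjusted p = 0.0912 with an estimated correlation). Among them were the forkhead factors Foxc2 (109 ± 36.9 against 11.4 ± 8.33, SD, n = 6, 2.19 ± 0.32, adjusted p = 0.000205), Foxl2 (1.76 ± 0.27, adjusted p = 0.000304) and Foxd1 (1.28 ± 0.30, adjusted p = 0.00989). The mesenchymal factor Twist1 rose too (1.41 ± 0.28, adjusted p = 0.00320). Tbx1, a regulator of head muscle, was at -0.52 ± 0.55 (adjusted p = 0.703), and at -0.98 (adjusted p = 0.147) without EOM 1. Its signals were low, at 46.7 ± 72.7 in EOM and 57.8 ± 49.7 in TA (SD, n = 6). Limb patterning genes other than Hox did not pass as a list (16 tested, 1 higher and 4 lower, 3 and 5 without EOM 1, camera adjusted p = 0.402). Tbx2 (-2.15), Tbx3 (-1.93) and Shox2 (-1.77, with its other tested probe set at -0.07) fell and Tbx15 (1.16) rose. The hind limb factor Pitx1 was at 0.02 ± 0.36 (adjusted p = 0.988), and at -0.12 (adjusted p = 0.859) without EOM 1. Its signals were 52.8 ± 25.5 in EOM and 53.2 ± 34.2 in TA (SD, n = 6), below the median of 92.1 over tested probe sets. Equal expression and a level near background in both muscles cannot be told apart there.

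Markers of muscle cells gave a mixed picture. Satellite cell and myoblast markers did not pass as a list (23 tested, 3 higher and 5 lower, and 5 and 6 when adjusted over the list alone, median -0.32, and -0.51 without EOM 1, camera adjusted p = 0.358, and adjusted p = 0.0236 with fry). The membrane protein Chodl (-2.92 ± 0.35, adjusted p = 2.86e-05), the receptor Notch3 (-2.63 ± 0.30, adjusted p = 1.38e-05) and the integrin Itga7 (-2.25 ± 0.37, adjusted p = 0.000536) fell. Met, the receptor of hepatocyte growth factor, rose (2.37 ± 0.45, adjusted p = 0.00216). Notch3 is also a receptor of pericytes and Itga7 is present in smooth muscle, whose markers fell with a median of -2.09. Myod1, the myoblast transcription factor, had signals of 31.3 ± 27.7 in EOM and 92.8 ± 52.3 in TA (SD, n = 6, -1.28 ± 0.41, adjusted p = 0.0678). It passed without EOM 1, EOM 5 or TA 1, at 0.0338 at the lowest of these fits. It also passed with array weights (-1.37, adjusted p = 0.0143), with the 3' to 5' ratio as a covariate (-1.44, adjusted p = 0.0271) and without EOM 1, TA 3 and TA 5 (-1.45, adjusted p = 0.0328). Pax3 was at -0.27 ± 0.45 (adjusted p = 0.841), and at -0.51 (adjusted p = 0.475) without EOM 1. Its mean signals were low, at 49.95 in EOM and 75.05 in TA. Pax7, Myf5 and Tbx4 lay below the level filter and were not tested. Limb-type myofibre genes gave 4 lower and 0 higher of 19 (5 lower when adjusted over the list alone, median -0.69, camera adjusted p = 0.00799, and adjusted p = 0.305 with an estimated correlation). They were the tropomyosins Tpm2 (-2.72 ± 0.37, adjusted p = 8.55e-05) and Tpm1 (-2.21 ± 0.46, adjusted p = 0.00471), which smooth muscle also uses, skeletal actin, Acta1 (-1.66 ± 0.46, adjusted p = 0.0292), and muscle phosphorylase, Pygm (-1.57 ± 0.35, adjusted p = 0.00777). Slow, developmental and extraocular myofibre genes did not pass (7 tested, 1 lower; median 0.10, and -0.011 without EOM 1, mean -0.35, with the test leaning lower, camera adjusted p = 0.703). The calsequestrin Casq2 fell (-2.53 ± 0.40, adjusted p = 0.000387). Myh13 was not analysed here. Genes of the dystrophin-associated complex gave 6 lower and 1 higher of 19 (7 and 1 when adjusted over the list alone, 6 and 3 without EOM 1, median -0.47, camera adjusted p = 0.0274, and adjusted p = 0.277 with an estimated correlation). The call ended without EOM 1, at 0.270. Its largest changes were caveolin 1, Cav1 (-3.72 ± 0.30, adjusted p = 4.48e-07), abundant in endothelium, Itga7 (-2.25), the laminin chain Lama5 (-2.17 ± 0.27, adjusted p = 4.10e-05) and the syntrophin Sntb1 (-1.73 ± 0.34, adjusted p = 0.00289).

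Among signalling pathways, Notch genes were lower in EOM. Of 20 tested 9 fell and 0 rose (10 fell when adjusted over the list alone, and 10 fell and 1 rose without EOM 1), with a median of -1.26 (camera adjusted p = 5.75e-06, and adjusted p = 0.0106 with an estimated correlation). The ligand Jag1 (-2.86 ± 0.50, adjusted p = 0.00103), the receptors Notch3 (-2.63) and Notch4 (-2.40 ± 0.37, adjusted p = 0.000319), and the pathway's target and inhibitor Nrarp (-2.41 ± 0.30, adjusted p = 3.66e-05) fell. The other tested probe set of Jag1 was at 0.08. Notch4 is an endothelial receptor and Notch3 one of mural cells. Wnt pathway genes gave 3 higher and 0 lower of 27 (5 higher when adjusted over the list alone, 7 higher and 1 lower without EOM 1). They were the Wnt antagonist Sfrp4 (2.51 ± 0.35, adjusted p = 0.000110), the R-spondin receptor Lgr5 (1.71 ± 0.37, adjusted p = 0.00594) and the ligand Wnt11 (1.40 ± 0.28, adjusted p = 0.00277). That list was near the threshold (median 0.12, camera adjusted p = 0.0444, and adjusted p = 0.327 with an estimated correlation). Leaving out any of EOM 0, EOM 3, EOM 6, TA 2, TA 5 or TA 6 ended its call, at up to 0.101. BMP, TGF-beta and myostatin genes went both ways (31 tested, 6 higher and 5 lower, 11 and 5 without EOM 1, camera adjusted p = 0.450). The ligands Bmp6 (-3.33 ± 0.33, adjusted p = 3.79e-06) and Bmp5 (-2.60 ± 0.34, adjusted p = 6.36e-05) and the BMP target Id1 (-2.02) fell. The latent TGF-beta binding protein Ltbp1 rose (2.05 ± 0.26, adjusted p = 3.74e-05). IGF, FGF, HGF and PDGF genes also went both ways (34 tested, 10 higher and 7 lower, and 11 and 9 when adjusted over the list alone, camera adjusted p = 0.205, and adjusted p = 0.0236 with fry). The vessel-stabilizing ligand Angpt1 (2.63 ± 0.33, adjusted p = 3.76e-05) and Igfbp5 (2.28 ± 0.30, adjusted p = 5.49e-05) rose, and the endothelial ligand Pdgfb fell (-2.73 ± 0.44, adjusted p = 0.000442).

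Interferon response genes leaned higher (27 tested, 2 higher and 1 lower, 5 and 1 when adjusted over the list alone, 10 and 1 without EOM 1, median 0.48, camera adjusted p = 0.00152, and adjusted p = 0.370 with an estimated correlation). Usp18 (1.41 ± 0.31, adjusted p = 0.00711) and Gbp2 (1.19 ± 0.29, adjusted p = 0.0121) rose. Cytokine and chemokine genes went both ways (26 tested, 4 higher and 6 lower, 11 and 8 without EOM 1, camera adjusted p = 0.489), the B cell chemokine Cxcl13 (2.36) and the alarmin Il33 (2.29) rising and Ccl9 (-2.29) and Ccl5 (-2.22) falling. Proliferation genes gave 1 lower of 27, Mcm3 (-0.95), with a median of -0.05 and a test that leaned higher (camera adjusted p = 0.988), and without EOM 1 they gave 2 higher and 1 lower, with a median of -0.18. Quiescence genes gave 1 lower of 20, Rgs5 (camera adjusted p = 0.489, and adjusted p = 0.0102 with fry), a pericyte gene, and 1 higher and 2 lower without EOM 1. Immediate early and dissociation stress genes gave 2 higher and 2 lower of 30 (5 and 3 without EOM 1, median -0.03, and 0.14 without EOM 1, mean 0.0011, camera adjusted p = 0.673). The transcription factor Maff rose (1.85 ± 0.24, adjusted p = 5.55e-05) and the small heat shock protein Hspb1 fell (-2.54 ± 0.29, adjusted p = 1.36e-05). Schwann cell and nerve markers gave 2 higher, Nefm and the growth cone protein Gap43 (2.39 ± 0.35, adjusted p = 0.000194), and 2 lower of 16 (camera adjusted p = 0.289). Of 7 adipocyte markers 2 fell, Pparg (-2.86) and lipoprotein lipase, Lpl (-1.86) (camera adjusted p = 0.142, and adjusted p = 1.08e-08 with fry). The 10 ocular surface, retina, gland and melanocyte markers tested (camera adjusted p = 0.942) and the 4 sex-linked genes (camera adjusted p = 0.729) did not pass, alone or as lists. Of 119 named genes that passed, 107 kept the call in each of the 12 fits with a single array left out. The other 12 lost it in some of these fits, where every array other than EOM 1 ended at least 1 call. The highest adjusted p was 0.0776 for Pdgfra, 0.0744 for Mcm3, 0.0729 for Acta1, 0.108 for Camp, 0.0706 for Cd14, 0.105 for Hoxb3, 0.112 for Hspa1a, 0.102 for Ier5, 0.119 for Ndufs8, 0.114 for Oas2, 0.107 for S100a9 and 0.0834 for Stmn2.

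**Figure D3:**
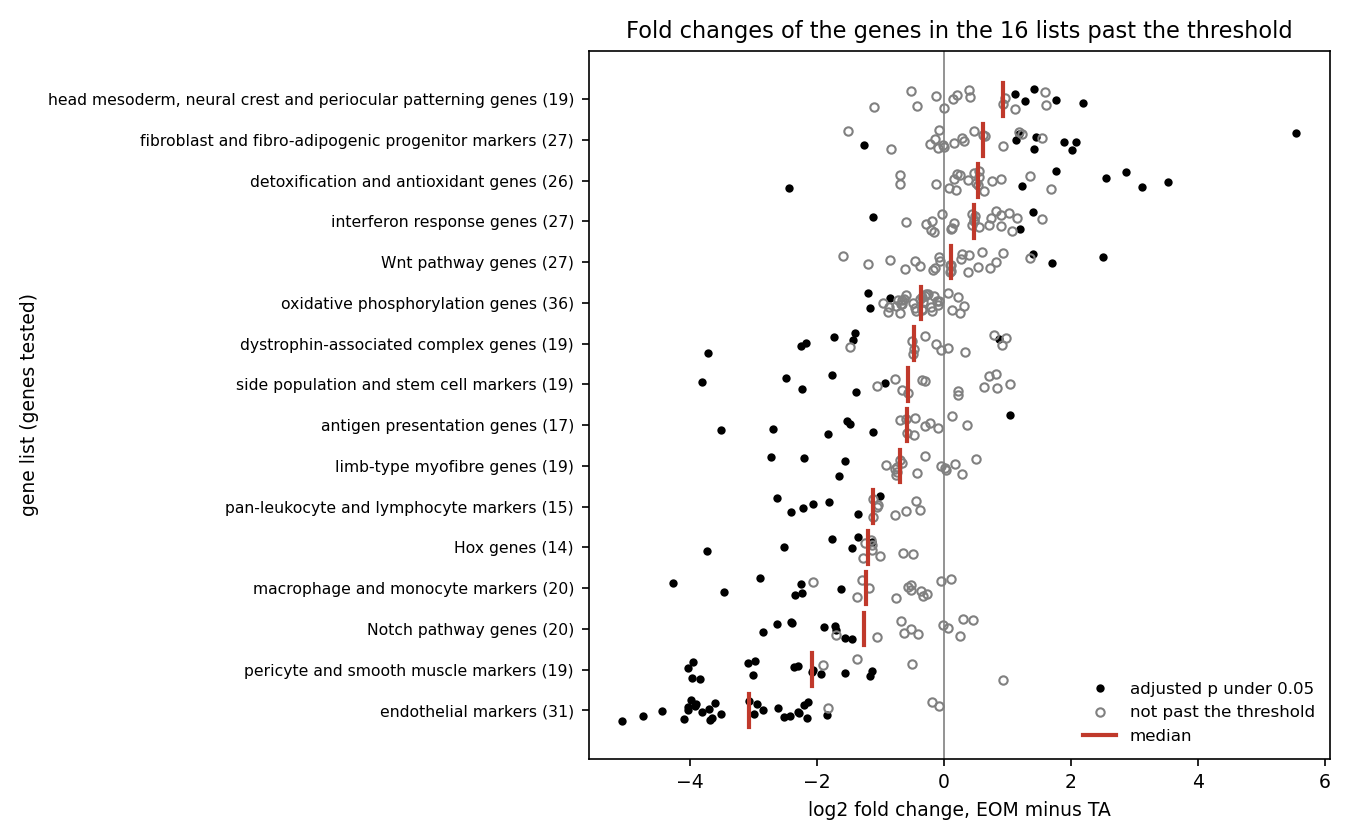
Log2 fold change (EOM minus TA, x axis) of every tested gene in the 16 lists that passed the camera test (y axis, number of genes tested in parentheses); filled points passed an adjusted p of 0.05, open points did not, and red bars are medians. The endothelial list has its median at -3.08 and the head and periocular list at 0.93.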

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

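The tests of endothelial and other cell shares, of the hybridization controls, and of EOM 1 gene by gene and for TA material were chosen after the results were seen, as was the comparison without EOM 1, TA 3 and TA 5; the other tests here were set down before the values they measure were seen.

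Endothelial and mural markers were lower in EOM. Without the 3 arrays with a median signal above 50 (EOM 1, TA 3 and TA 5) the median log2 fold change of the endothelial list was -3.42 (SE over genes 0.217). With the 3' to 5' ratio as a covariate it was -3.27 (SE over genes 0.207), against -3.08 with all arrays. These SEs treat the genes of a list as independent, though their estimated correlation was 0.399, so they understate the uncertainty. The fall did not shrink without the 3 arrays, which argues against those arrays as the whole cause. The 3' to 5' ratios did not differ detectably between the groups. The covariate was therefore unlikely to change the median much and cannot decide on RNA quality. A lower share of endothelial cells alone would raise all other markers alike, but the leukocyte median lay below the fibroblast median (difference -1.73, SE over genes 0.319). The directions of both lists were known when this test was chosen, and its SE too treats genes as independent. The difference goes against that explanation but, chosen in this way, does not exclude it. Without those 3 arrays 98.8% of 85 endothelial, mural, macrophage and leukocyte markers lay below 0, but this was known of their lists when the test was chosen, and lower expression in each cell predicts it too. Lower shares of several cell types and lower expression per cell therefore cannot be told apart, and a difference between the muscles themselves remains open and was not tested.

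EOM 1 stood apart from the other EOM arrays: on an axis from the mean of the TA arrays (0) to the mean of the other EOM arrays (1), over 2675 genes called without EOM 1, it lay at 0.486, against 0.823 to 1.05 for the other EOM arrays and -0.153 to 0.150 for the TA arrays. All arrays but EOM 1 helped to call these genes, which favours positions near 0 and 1 for them, so the positions are not like for like. The position of EOM 1 is under the midpoint of 0.5 set beforehand as the bound for a wrong label, and the reading of this test was changed from favouring a wrong label to undecided after the value was seen. Of 1809 genes chosen without EOM 1 for no overlap between the other arrays of the groups, 48.1% had EOM 1 beyond all TA arrays on the EOM side (31.5% of the higher and 64.4% of the lower genes, against 10.1% to 30.5% for TA arrays), short of the 50% set for excluding a wrong label. The TA arrays had helped to call the genes, which favours low percentages for them. Over 98 genes at least 8-fold lower without EOM 1, however, its median share of the TA signal was 0.0326 (SE over genes 0.0105), against 0.636 to 1.26 for each TA array set against the others, which argues against a TA sample, or an equal mixture with TA material, in its place. A small share of TA material or a sample from outside the 2 groups remains open, no biological explanation was tested, and a low yield of labelled target is a candidate explanation, since the hybridization control signal of EOM 1 was 8530, against at most 6225 on the other arrays. TA 3 and TA 5, at 6225 and 3883, lay at -0.0190 and -0.153 on the axis, so a high control signal did not go with a middle position there. The 18S ribosomal RNA control was at 51292 on EOM 1, against at most 2250 on the other arrays.

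Chance was an unlikely but not excluded cause of the number of probe sets that differ. Of 100 splits of the 12 arrays into 6 and 6 that were tried, the real one included, 2 gave as many as the real 2225. The highest other split gave 2318, and it joined the 5 EOM arrays other than EOM 1 with TA 0, so it differs from the real one by an exchange of EOM 1 and TA 0. For probe sets that differ at least 2-fold 2 of 100 splits gave as many as the real 2017, the other being the same split with 2087. For lists 1 of 100 splits gave as many as the real 16. The highest other splits had 15, and each joined 5 EOM arrays with 1 TA array, so they nearly keep the muscles apart. Lists also passed in some splits with equal numbers of arrays of each muscle. Joining EOM 0, EOM 2 and EOM 6 with TA 2, TA 3 and TA 6 gave 9 lists and 0 probe sets. Joining them with TA 0, TA 1 and TA 6 gave 0 lists. Camera adjusted p-values with the preset correlation can therefore be too small.

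In each group of 6 arrays, an array was noted when its gap to the nearest other array was a larger share of the range of the group than Dixon's 95% limit for 6 values. Chance notes about 1 in 20 groups. EOM 1 was noted in 5 of 6 array measures: median signal (0.849), hybridization controls (0.895), the 3' to 5' beta-actin ratio (0.795), the 18S ribosomal RNA control (0.984, at 51292) and the mean correlation with its own group (0.963). Among 160 genes, 45 of 320 groups were noted, where chance gives 16, and 30 of the 45 came from EOM 1. EOM 1 was the lowest EOM array for Epyc 0.859, Phex 0.782, Lgi1 0.797, Gsta4 0.721, Nefm 0.674, Abcg2 0.679, Met 0.634, Fbln1 0.655, Ier5 0.767, Il33 0.790, Jag1 0.795, Angpt1 0.804, Cyp1b1 0.904, Cd34 0.834, Pdgfra 0.700, Col4a5 0.848, Col4a6 0.691, Igf1 0.807, Fgf7 0.798, Foxp2 0.827, Nr2f1 0.631 and Cthrc1 0.686. It was the highest for Tbx3 0.688, Cd74 0.803, Dpep1 0.821, L1cam 0.687, Oas2 0.842, Nrarp 0.710, Pdgfrb 0.768 and Hoxa10 0.641. The other 15 were Irx2 (TA 3 highest, 0.665), Met (TA 3 lowest, 0.626), Foxl2 (EOM 6 highest, 0.803), S100a9 (EOM 5 highest, 0.754), Camp (EOM 5 highest, 0.669), Ano1 (EOM 5 highest, 0.669), Hspb1 (TA 2 lowest, 0.728), Maff (EOM 5 lowest, 0.745), Maff (TA 5 lowest, 0.872), Ier5 (TA 3 lowest, 0.699), Sfrp4 (TA 2 lowest, 0.642), Lgr5 (TA 1 highest, 0.670), Col4a1 (TA 3 lowest, 0.823), Scx (TA 3 highest, 0.757) and Kctd1 (TA 3 highest, 0.843).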

How the results depend on the processing

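Leaving out EOM 1, TA 3 and TA 5 together was chosen after the data were seen; the other alternatives were planned. Of the fold changes of named genes under all alternatives, 3736 kept their direction and their side of the threshold, 232 were no longer past it, 33 came past it (of Abcb1a, Cd34, Hoxa10, Hoxc10, Myod1, Pdgfrb and Pecam1) and 15 reversed. The cause was not tested for any change below, except that leaving out arrays or probe sets leaves fewer of them.

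The number of probe sets that differ (2225) was 5488 with array weights, where EOM 1 had the lowest weight (0.126), 4675 without the 3 arrays and 1445 with median centring. It ranged from 1381 to 4361 with an array or a replicate number left out, the highest without EOM 1. The number that differ at least 2-fold (2017) was 3091 with array weights and ranged from 1377 to 3192 with an array or number left out. Of 16 lists past the threshold 3 stayed past it with an estimated correlation.

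With an estimated correlation the adjusted p was 0.0912 for the side population, head and periocular, pan-leukocyte, fibroblast, oxidative phosphorylation and detoxification lists, 0.0965 for Hox, 0.147 for macrophage, 0.219 for antigen presentation, 0.277 for the dystrophin-associated complex, 0.305 for limb-type myofibre, 0.327 for Wnt pathway genes and 0.370 for interferon response genes. With fry, which tests a list against no change rather than against the other genes, 19 lists were past the threshold. Interferon, at 0.0940, was not, while adipocyte (1.08e-08), quiescence (0.0102), satellite cell and IGF, FGF, HGF and PDGF genes (both 0.0236) came past it. With an array or number left out the interferon list was between 4.32e-05 and 0.0579, the highest without number 3. With array weights antigen presentation and side population were both at 0.0578 and dystrophin-associated genes at 0.107; without the 3 arrays these were at 0.0619, 0.0658 and 0.127. With 60% of probe sets filtered dystrophin-associated complex genes were at 0.154 and Wnt genes at 0.0897. Wnt genes were at 0.0695 with the 3' to 5' ratio as a covariate, 0.0505 with median centring and 0.0708 with quantile normalization. With an array or number left out the adjusted p ranged from 0.0212 to 0.101 for Wnt, from 0.00570 to 0.287 for dystrophin-associated and from 0.0127 to 0.0625 for side population genes.

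Pax3 and Pitx1, both near 0 and not past the threshold, changed sign. Pax3 (-0.27) was at 0.087 with the covariate and 0.12 without the 3 arrays, and between -0.62 and 0.074 with an array or number left out. Pitx1 (0.02) was at -0.015 with array weights and between -0.15 and 0.23 with an array or number left out.

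No pairing of the arrays by replicate number was detected. The mean correlation of same-numbered arrays, after removing group means, was -0.0544 against 0.0308 for different numbers. Of the 6 EOM arrays, 1 was closest to the TA array of its own number. The correlation was 0.143, 0.0276 and 0.157 for numbers 0, 2 and 6. It was -0.255, -0.317 and -0.0829 for numbers 1, 3 and 5, which hold EOM 1, TA 3 and TA 5. Because those arrays weigh on the mean, a pairing cannot be excluded. With the number as a fixed block 1632 probe sets passed and the list of Wnt pathway genes was at 0.0532; as a random block 1955 passed. The array signal has no depth; values near the background, where the added 16 weighs most, are the least certain.

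The mean correlation within groups exceeded that between groups by 0.0319 over all probe sets, 0.113 over the upper 25%, 0.0586 with Spearman correlation and 0.0665 without the 3 arrays, against 0.0535.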

Other observations

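The genes in the next 2 paragraphs were chosen after their values were seen, as were the lists they form; the list of tendon genes was written after 6 of its members had been seen, and its 2 tests before their values, while the comparison of the 13 other genes without EOM 1, TA 3 and TA 5 was chosen after the results were seen.

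The 4 Iroquois genes tested were all higher in EOM: Irx3 (3.80 ± 0.37, adjusted p = 3.23e-06), Irx2 (3.62), Irx5 (3.41) and Irx1 (2.57 ± 0.43, adjusted p = 0.000631). These transcription factors pattern the body axes and the nervous system. Foxp2 (2.82 ± 0.40, adjusted p = 0.000155) and the nuclear receptor Nr2f1 (2.72 ± 0.22, adjusted p = 4.48e-07) were higher as well.

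Collagen IV chains went in both directions. Col4a1 (-2.18 ± 0.26, adjusted p = 2.04e-05) and Col4a2 (-3.29), the chains of most basement membranes, were lower in EOM, Col4a5 (3.13 ± 0.39, adjusted p = 4.10e-05) and Col4a6 (3.26 ± 0.46, adjusted p = 0.000117) were higher, and Col4a3 (-0.16, adjusted p = 0.922) and Col4a4 (0.09, adjusted p = 0.920) did not pass. The 7 secreted growth and survival factors picked were higher in EOM, among them Vegfd (2.90 ± 0.37, adjusted p = 4.10e-05), Gdnf (2.60 ± 0.45, adjusted p = 0.000821), Fgf7 (2.10 ± 0.35, adjusted p = 0.000604), Hgf (1.91 ± 0.42, adjusted p = 0.00710), Igf1 (1.90 ± 0.48, adjusted p = 0.0170) and Bdnf (1.75 ± 0.50, adjusted p = 0.0368).

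Of 20 listed tendon genes 19 were tested and 12 were lower in EOM, with no enrichment test run on the list, and tendon cells in the TA preparations are a candidate explanation. The 13 that had not been seen had a median log2 fold change of -1.47, with 6 lower, 0 higher and 7 not past the threshold in limma, and 12 of the 13 below 0 (Kctd1 was at 0.11 and Cthrc1 at -0.16). Among these 13, Scx was at -0.97 ± 0.35 and did not pass (adjusted p = 0.109), and Mkx was at -1.47 ± 0.40 and passed (adjusted p = 0.0290). Without EOM 1, TA 3 and TA 5 the median of these 13 was -1.53 (SE over genes 0.231), and that of all 19 was -1.82 (SE over genes 0.285), against -2.03 for all 19 with all arrays, which argues against those arrays as the whole cause. Fmod had the highest signal of the listed genes, which also depends on its probes, at 42452 ± 29387 in TA and 4581 ± 3421 in EOM (SD, n = 6), and Fmod and Tnc are also on the extracellular matrix list. The side population gate would remove tendon cells that do not export the dye, and a difference between the muscles themselves was not tested.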
